A study of Arabidopsis thaliana with 4 samples.

How the data were processed

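RNA-seq was carried out on 4 libraries of whole Col-0 seedlings, 2 from seedlings of 2 dpg and 2 from seedlings of 6 dpg. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit, which does not mark the strand. Per the submitters' processing notes, CASAVA 1.8, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0 were used, with roles not given; the genome build and annotation are not given in the sources used here.

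The deposited table gives for each gene a read count in each library, so named in the headers and taken as not normalized because the values are whole numbers. It also holds the authors' FPKM per library and per age, which were used only to recover library totals. Another 2 columns hold a signal that the authors made, the mean over an age of counts divided by a size factor. Their headers name other days, but their values are exact combinations of the day 6 and day 2 counts (largest deviation 5.01e-05), with size factors of 1.12, 0.924, 1.10 and 0.895. The authors' p-value and adjusted p-value per gene come from the same deposited table, and the authors' log2 fold change column was not used because some cells held no number. By the authors' deposited values, 7373 genes have an adjusted p under 0.05, 3786 higher and 3587 lower at 6 dpg; 7338 of them were also called here, all in the same direction, and the other 35 were not among the genes tested. A second deposited table assigns 1369 genes to 77 families, 1094 as transcription factors and 275 as regulators; 1110 of them were in the count table.

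The count table as held ends on chromosome 5 at position 3070933 and has no genes of the plastid or mitochondrion. It holds 21408 of 27444 nuclear coding genes of the reference (78.0%), and 4311 of its 26784 genes had no read. Because the sum of a partial table is not a library's depth, the total behind each FPKM column was recovered from count, FPKM and gene length. Among genes with more than 200 reads, 66.7 to 67.8% gave the same total within 0.01%: 26570983 and 20587872 for 2 dpg replicates 1 and 2 and 22745278 and 18330153 for 6 dpg replicates 1 and 2, of which the rows held make up 79.9 to 81.0%. A count of 3 at these totals corresponds to 0.113 to 0.164 CPM. Intervals and floors cover counting error only.

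Symbols were taken from the reference annotation where a locus matched (26407 genes) and otherwise from the table, in which 14 gene names had been turned into dates. Coordinates are those of the authors' table. Genes overlapping another gene are uncertain: of 253 coding genes with over 90% of their span overlapped, 62.8% had no read in any library, against 8.57% of the 18420 coding genes without overlap. Reads of near-identical copies can be split among them or lost.

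Ages were compared with edgeR 4.0.16 in R 4.3.3 (TMM factors on the recovered totals, filterByExpr with a minimum count of 10, quasi-likelihood test, age as the only term, Benjamini-Hochberg adjusted p under 0.05). The filter removed 10624 genes and left 16160. The biological coefficient of variation was 11%. CPM use the recovered totals times the TMM factors. Between the replicates of an age, chi-square per degree of freedom over genes was 17.2 at 2 dpg and 6.22 at 6 dpg, so no library was a copy of another. Families with 10 or more tested members and gene lists with 5 or more were tested with camera (limma 3.58.1), with a preset inter-gene correlation of 0.01 and, as the alternative, an estimated one, and also with fry. DESeq2 1.42.0 was the alternative test for genes. Transcription factor genes were compared with other genes by Fisher's exact test. The main tests of genes, families and lists, the lists themselves and the rule for naming genes were fixed before the data were examined. Fry, the Fisher test of transcription factor against other genes, and camera on the whole transcription factor set were not in that plan. Some tests of technical explanations were chosen later, as stated with them. The 29 lists held 455 loci, of which 369 were in the table: 366 matched by symbol and 3 by description. They covered the pathways and cell types of seedlings described here, with senescence, heat shock, endosperm and seed coat, and seed storage as lists too small to test.

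Named genes were, in each list, up to 2 called genes with the largest rise and up to 2 with the largest fall, with key genes of a pathway also given as values; the 10 transcription factor genes with the largest rise and the 10 with the largest fall at a mean normalized count of 20 or more and without overlap between ages; the 5 other genes with a symbol that rose most and the 5 that fell most at a mean normalized count of 100 or more; and in each called family the member with the smallest adjusted p. The rule took 120 genes.

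The fit was tested on simulated counts for 16008 genes with the means, dispersion and library sizes of the comparison of 6 with 2 dpg. At an absolute log2 fold change of 1, edgeR recovered 80.8% of changed genes and DESeq2 75.8%; at 2 they recovered 98.0% and 92.0%. Of 199 edgeR calls 21 were false (10.6%), above the 5% aimed at. Of the 16008 simulated genes only 99 changed by 1 and 100 by 2, whereas 56.6% of tested genes were called in the data. Recovery and the false share depend on that fraction and do not carry over to the real calls. Alternatives were another scaling, test, count filter and threshold, a replicate block, each library left out, and, chosen after seeing the data, column sums as library sizes, scaling on ribosomal protein genes, and offsets that remove a lowess trend of each library on log2 gene length.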

Results

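Messenger RNA was sequenced from whole wild-type Arabidopsis thaliana seedlings of the Col-0 accession at 2 ages, 2 and 6 days post germination (dpg), with 2 libraries per age. The seedlings grew on half-strength Murashige and Skoog plates with 0.5% sucrose at 22 °C under a 12-h photoperiod, and the series asks which transcription factor genes differ in expression during early growth. The table of reads per gene covered chromosomes 1 to 4 and chromosome 5 up to position 3070933. Genes further along chromosome 5 and genes of the plastid and mitochondrion were not analysed here. It held 26784 genes. The reads on them totalled 21217252 and 16478848 in 2 dpg replicates 1 and 2 and 18336468 and 14845619 in 6 dpg replicates 1 and 2. Expression is given in CPM, counts scaled to library size, as mean ± SD with n = 2 at each age. Fold changes are 6 dpg relative to 2 dpg.

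Between 2 and 6 dpg most tested genes of fat reserve breakdown, of the photosynthetic light reactions, of cell division, of wall loosening, of root hairs and of flavonoid synthesis fell. These lists were called with the preset correlation and none with an estimated one (camera adjusted p = 0.464 to 0.691 with an estimated correlation). The estimate rested on 2 residual degrees of freedom and so had little power. In the same interval 520 transcription factor and regulator genes rose and 213 fell. The 6 dpg level of ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, was 33.0 ± 0.206 CPM, against 2290 ± 796 CPM at 2 dpg. MYBL2 (AT1G71030), which encodes a repressor of anthocyanin synthesis, rose from 2.65 ± 0.159 to 62.2 ± 6.86 CPM. Of 16160 genes tested with edgeR, 9153 (56.6%) changed at an adjusted p under 0.05, 4568 higher and 4585 lower at 6 dpg. Changes of at least 2-fold were found for 1879 of the higher and 2021 of the lower genes, and changes of at least 8-fold for 166 and 131. In 80.6% of the tested genes both libraries of one age lay above both of the other, where chance gives 33.3%. Log2 CPM across the tested genes correlated at Pearson r = 0.988 between the 2 dpg libraries and 0.990 between the 6 dpg libraries, against 0.895 to 0.918 across ages (genes are not independent replicates). No label says whether the libraries of an age came from separate plantings, so p-values measure only the spread between these libraries, which may be technical. Directions are relative to the bulk of genes. When libraries were scaled on 16 cytosolic ribosomal protein genes, a choice made after seeing the data, the median log2 fold change of all genes moved from 0.00 to 0.44. The calls then became 6494 higher and 1729 lower. Those 16 genes had themselves fallen (list median -0.43), so this upward shift follows by construction. Values under this scaling show only how directions depend on the reference genes.

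Outside the transcription factors and the fixed lists, the largest falls among well-expressed genes included 2 expansin genes. EXPA17 (AT4G01630) fell from 18.3 ± 6.55 to 0.456 ± 0.355 CPM and EXPB1 (AT2G20750) from 37.1 ± 7.80 to 1.65 ± 0.376 CPM. The transporter gene UMAMIT36 (AT1G70260) fell from 20.3 ± 0.435 to 0.568 ± 0.0795 CPM. The desaturase-like gene ADS4 (AT1G06350) fell from 30.2 ± 6.37 to 1.28 ± 0.0730 CPM and the cysteine proteinase gene CP1 (AT4G36880) from 126 ± 15.1 to 5.98 ± 0.807 CPM. The largest rises were those of CYP71A12 (AT2G30750), a cytochrome P450 of the camalexin pathway, with log2 fold change 5.52 ± 0.96 (SE, edgeR adjusted p = 0.0013), and of HIS1-3 (AT2G18050), a linker histone gene, with 5.51 ± 0.35. CYP71A12 differed widely between the 6 dpg libraries, at 3.16 and 16.4 CPM (9.80 ± 9.38 CPM). So did the potassium transporter gene HAK5 (AT4G13420), at 5.87 and 21.4 CPM, which rose from 0.340 ± 0.0170 to 13.6 ± 11 CPM. The cytochrome P450 genes CYP706A6 (AT4G12320) and CYP71B4 (AT3G26280) rose from 0.395 ± 0.153 to 13.8 ± 0.0682 CPM and from 0.518 ± 0.0212 to 17.4 ± 3.06 CPM, with closely placed replicates.

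**Figure D1:**
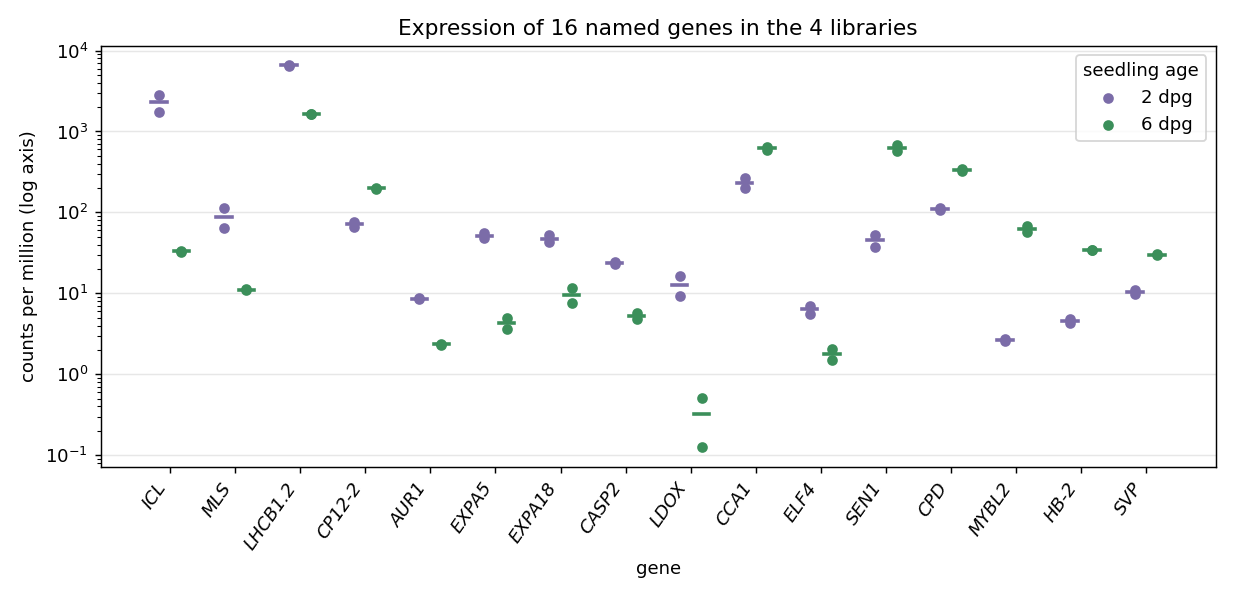
CPM (log axis) of 16 named genes in each of the 4 libraries, where points are libraries, coloured by seedling age, and horizontal bars are the mean of the 2 libraries. ICL drops from a mean of 2290 to 33.0 CPM and MYBL2 climbs from 2.65 to 62.2 CPM, with no overlap between ages for the genes drawn.

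The fold changes followed gene length. The median log2 fold change was -0.28 for the 3278 tested genes of 500 to 1000 bp, -0.01 for the 3853 genes of 1500 to 2000 bp and 0.53 for the 367 genes of 4000 to 6000 bp (Spearman 0.231 across genes). The 2 dpg libraries differed from each other along the same axis. Replicate 2 over replicate 1 had a median log2 ratio of -0.08 in the first of these classes and 0.31 in the last (Spearman 0.232). For the 6 dpg libraries the same medians were -0.07 and 0.06 (Spearman 0.167). A fit with offsets that removed this trend from each library, added after the data were seen, called 9142 genes, of which 8062 were shared with the 9153. Without 2 dpg replicate 1 the count was 8250.

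**Figure D2:**
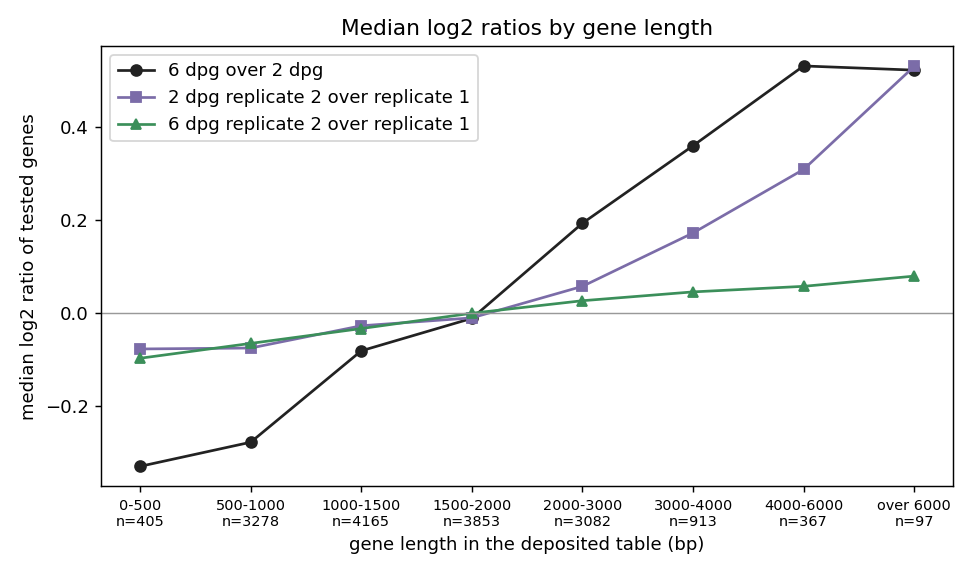
Median log2 ratio of tested genes (vertical axis) in 8 classes of gene length in bp (horizontal axis, with the number of genes per class), for 6 dpg over 2 dpg and for replicate 2 over replicate 1 at each age. The medians of 6 dpg over 2 dpg run from -0.33 in the shortest class to 0.52 in the longest, and those between the 2 dpg libraries from -0.08 to 0.53.

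Most genes for the use of stored oil fell, and a few rose. Of 16 tested genes of storage lipid mobilisation and the glyoxylate cycle, 11 fell and 3 rose (4 rose when adjusted over the list alone). Besides ICL, which fell by 6.12 ± 0.26 on the log2 scale (SE, edgeR adjusted p = 2.57e-06), the malate synthase gene MLS (AT5G03860) fell from 88.2 ± 33.4 to 11.1 ± 0.164 CPM. The beta-oxidation genes MFP2 and ACX3 also fell (log2 fold change -0.98 and -0.88). PMDH2, a peroxisomal malate dehydrogenase gene, and SDP1, the gene of a triacylglycerol lipase, rose by log2 1.34 and 0.93. The list median was -0.55 (camera adjusted p = 0.0388; adjusted p = 0.691 with an estimated correlation). The call was also lost, narrowly, among genes with a mean normalized count of 20 or more (adjusted p = 0.0501). Members of this list are long, and genes of their lengths had a trend of 0.18, opposite to the fall. Under ribosomal protein scaling the list median was -0.10.

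Nuclear genes of the photosynthetic light reactions were lower at 6 dpg in 28 of 32 cases, and none was higher, at a list median of -0.71 (-0.29 under ribosomal protein scaling). The chlorophyll a/b-binding protein gene LHCB1.2 (CAB3, AT1G29910) fell from 6571 ± 73.6 to 1640 ± 20.3 CPM, LHCB4.1 (AT5G01530) from 4453 ± 200 to 1827 ± 57.6 CPM and LHCB6 from 4816 ± 113 to 2063 ± 52.6 CPM. LHCB1.2 has near-identical neighbours, LHCB1.1 and LHCB1.3, among which reads can be split or lost. Both fell as well (log2 fold change -0.98 and -1.2). The camera adjusted p of the list was 1.5e-08, but adjusted p = 0.563 with an estimated correlation. Its members are short, with a length trend of -0.14. After removal of that trend 24 members fell, at a list median of -0.58. Chlorophyll biosynthesis genes fell in 5 of 11 cases with none higher. GSA2 (AT3G48730, glutamate-1-semialdehyde aminomutase) fell from 390 ± 34.9 to 93.6 ± 3.52 CPM and CHLI1 (AT4G18480, a magnesium chelatase subunit) from 887 ± 20 to 341 ± 10.9 CPM. The median of this list, -0.29 (camera adjusted p = 0.00823; adjusted p = 0.546 with an estimated correlation), turned to 0.13 under ribosomal protein scaling. The Calvin cycle list had 6 genes higher and 2 lower of 14, a median of 0.09 (0.52 under ribosomal protein scaling) and no call (camera adjusted p = 0.457). CP12-2 rose from 71.4 ± 7.83 to 199 ± 4.07 CPM and phosphoribulokinase (PRK) from 896 ± 146 to 1609 ± 80.8 CPM. PGK1 and TKL-1 fell (log2 fold change -0.76 and -0.39), but the sign for TKL-1 turned under ribosomal protein scaling. The Rubisco small subunit gene RBCS1A stood at 16940 ± 394 and 13620 ± 866 CPM (edgeR adjusted p = 0.075).

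Cell division and wall-loosening genes were lower at 6 dpg. Of 23 cell cycle and DNA replication genes, 19 fell (20 adjusted over the list alone), at a median of -1.0 (-0.59 under ribosomal protein scaling). The Aurora kinase gene AUR1 (AT4G32830) fell from 8.58 ± 0.0877 to 2.34 ± 0.0170 CPM. The B-type cyclin gene CYCB1;3 fell from 4.92 ± 0.567 to 1.74 ± 0.286 CPM and CDC20.1 from 28.0 ± 2.56 to 10.1 ± 0.509 CPM. The camera adjusted p was 2.21e-05 (adjusted p = 0.464 with an estimated correlation). Among 15 expansin and xyloglucan endotransglucosylase/hydrolase (XTH) genes, 12 fell and 2 rose (3 rose adjusted over the list alone), with camera adjusted p = 1.67e-05 (adjusted p = 0.673 with an estimated correlation). EXPA5 (AT3G29030) fell from 51.8 ± 5.31 to 4.29 ± 0.885 CPM and XTH31 (AT3G44990) from 300 ± 72.0 to 45.1 ± 5.58 CPM. Against the trend XTH15 and XTH24 rose from 54.4 ± 5.86 to 181 ± 48.0 CPM and from 104 ± 12.3 to 329 ± 42.7 CPM. Cytosolic ribosomal protein genes fell in 10 of 16 cases with none higher, among them RPS6 (log2 fold change -1.01) and SAC52 (-0.67). This list was not called (camera adjusted p = 0.0696, and 0.00119 without 2 dpg replicate 2). Its members carry a length trend of -0.21, and 5 of them were lower with length-adjusted offsets.

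Root genes also fell. All 6 tested root hair genes did so (camera adjusted p = 8.23e-06; adjusted p = 0.464 with an estimated correlation). EXPA18 (AT1G62980) fell from 47.5 ± 6.57 to 9.60 ± 2.72 CPM and the root hair regulator RHD6 (AT1G66470) from 6.68 ± 0.282 to 1.62 ± 0.171 CPM. EXPA18 and EXPA7 belong to both this list and the wall-loosening list. Of 12 genes of the root endodermis, root meristem and root transport, 7 fell and 2 rose (camera adjusted p = 0.00978; adjusted p = 0.546 with an estimated correlation). The Casparian strip gene CASP2 (AT3G11550) fell from 24 ± 0.983 to 5.28 ± 0.659 CPM, and CASP1 from 81.5 ± 15.1 to 18.7 ± 0.782 CPM. The nitrate transporter gene NRT2:1 (AT1G08090) fell from 1.73 ± 0.453 to 0.0928 ± 0.0135 CPM. The iron transporter gene IRT1 (AT4G19690) moved the other way, from 2 reads over both 2 dpg libraries to 88 over both 6 dpg libraries. The ratio was 44.7 (95% exact interval 12.0 to 375, counting error only). The phosphate exporter gene PHO1 rose by log2 0.55. Of 7 xylem and secondary wall genes, 3 fell, PAL1 and XCP1 most (log2 fold change -1.63 and -1.11), with no call for the list (camera adjusted p = 0.219).

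Flavonoid and anthocyanin genes fell in 7 of 8 cases (camera adjusted p = 2.11e-05; adjusted p = 0.673 with an estimated correlation). LDOX (AT4G22880, anthocyanidin synthase) fell from 12.8 ± 4.89 to 0.318 ± 0.274 CPM and the flavonol synthase gene FLS1 (AT5G08640) from 109 ± 16.1 to 16 ± 2.98 CPM. The anthocyanin regulator PAP1 (AT1G56650) fell from 95 reads over both 2 dpg libraries to 3 reads over both 6 dpg libraries, 31.1-fold (95% exact interval 10.3 to 154). F3H (AT3G51240, chromosome 3, 19025192 to 19026872 as listed by the authors) had 0 reads in all 4 libraries. Of its span 94.5% is overlapped by AT3G51238 on the opposite strand, also at 0. In the defence list 6 of 12 genes rose and 1 fell (8 and 1 adjusted over the list alone). The pathogenesis-related gene PR5 (AT1G75040) had 0 reads at 2 dpg and 78 over both 6 dpg libraries, 26.4-fold higher against a floor of 3 reads over the 2 dpg group (95% exact lower limit 21). The camalexin pathway gene CYP71A13 rose from 0.162 ± 0.0553 to 2.71 ± 0.655 CPM, and EDS16 (isochorismate synthase) fell from 29.8 ± 0.839 to 11.6 ± 0.327 CPM. The list median was 1.12, the same with PR5 at its bound. The list was not called (camera adjusted p = 0.0578), but it was with a replicate block (0.0159) and without 6 dpg replicate 1. CYP71A13 and CYP71A12 are neighbouring copies between which reads can be split or lost. Of 8 glucosinolate genes, 3 rose, with CYP79B3 and MYB51 each at log2 0.86, and SUR1 fell by 0.34 (camera adjusted p = 0.501). The sign for SUR1 turned under ribosomal protein scaling. In the low-oxygen list 1 gene rose (ERF73, log2 1.02) and 1 fell (HB1, log2 -0.81) of 7. Its median of -0.14 and the direction of its set test, up, differ in sign (camera adjusted p = 0.909), and the median turned to 0.35 under ribosomal protein scaling.

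Among hormone genes, those of ethylene signalling rose in 7 of 9 cases (8 adjusted over the list alone). EIN3, the main transcriptional activator of the response, rose from 113 ± 1.41 to 205 ± 4.69 CPM. ERF1 rose by log2 1.99 but stayed under 1 CPM, at 0.167 ± 0.120 and 0.664 ± 0.292 CPM. The list was called (camera adjusted p = 0.0388; adjusted p = 0.673 with an estimated correlation). The call was lost with a replicate block (0.0525), among genes with a mean normalized count of 20 or more (0.0501) and with length-adjusted offsets (0.182). It was also lost without 6 dpg replicate 2. Genes of these lengths had a trend of 0.20. In the brassinosteroid list 4 of 7 genes rose (camera adjusted p = 0.0578, and 0.0469 without 2 dpg replicate 1). The synthesis genes CPD (AT5G05690) and BR6OX2 (AT3G30180) rose from 110 ± 3.69 to 334 ± 9.12 CPM and from 21.4 ± 2.57 to 56.9 ± 2.87 CPM. Gibberellin genes had 1 higher and 5 lower of 12 (camera adjusted p = 0.0889). GA20OX1, a synthesis gene, and the DELLA gene RGL2 fell (log2 fold change -2.74 and -1.8), whereas the DELLA gene GAI rose by 0.48. The list median of -0.36 turned to 0.10 under ribosomal protein scaling. Of 20 auxin genes 6 rose and 4 fell (camera adjusted p = 0.749). The response genes IAA29 and IAA2 rose by log2 2.31 and 1.91, and IAA19 and GH3.3 fell (-1.85 and -1.04). Of 10 cytokinin genes 4 rose and 3 fell (camera adjusted p = 0.909; median 0.24, or 0.68 under ribosomal protein scaling, mean -0.02). The response regulator gene ARR7 and the oxidase gene CKX4 rose by log2 1.28 and 1.70, and the response regulator genes ARR3 and ARR15 fell (-1.87 and -1.83). In the abscisic acid list 3 genes rose and 1 fell of 9, with HB-12 and HAB1 at log2 1.67 and 1.16 and COR47 at -1.12 (camera adjusted p = 0.449).

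Several morning genes of the circadian clock rose, and 2 of 3 tested evening genes fell. The labels give no hour of collection. For genes with a daily rhythm, in this and other lists, age and harvest time therefore cannot be told apart. The morning-phased genes CCA1 (AT2G46830) and LHY (AT1G01060) rose from 232 ± 48.1 to 621 ± 34.8 CPM and from 535 ± 80.2 to 1221 ± 28.1 CPM. PRR7 rose by log2 2.28 and LNK2 (AT3G54500) by 1.52. The evening genes ELF4 (AT2G40080) and LUX (PCL1) fell from 6.32 ± 0.973 to 1.77 ± 0.388 CPM and from 28.2 ± 2.45 to 11.9 ± 1.31 CPM. The evening gene GI (AT1G22770) had a log2 fold change of -0.39, with overlapping libraries (edgeR adjusted p = 0.204). Of 10 clock genes 6 rose and 2 fell, and the list was not called (camera adjusted p = 0.0578). It was called without 2 dpg replicate 1, 2 dpg replicate 2 or 6 dpg replicate 2 (0.0353, 0.00422 and 0.0349). Its members carry a length trend of 0.19. Of 16 light signalling genes 8 rose and 2 fell (camera adjusted p = 0.0578, and 0.0261 without 2 dpg replicate 2). The shade-responsive genes PIL1 and HFR1 rose by log2 1.93 and 1.34, and PIF4 and LZF1 fell (-0.87 and -0.56). Flowering and phase change regulators had 5 higher and 3 lower of 11 (6 and 4 adjusted over the list alone; camera adjusted p = 0.449). The MADS-box gene AGL24 rose by log2 2.58 and SPL4 by 1.57, while SPL15 and SMZ, a repressor of flowering, fell (-1.36 and -0.97). In the trichome and stomatal list 2 genes rose and 4 fell of 9 (camera adjusted p = 0.749). FMA (AT3G24140), the regulator of guard cell identity, rose from 7 ± 1.26 to 33.0 ± 1.14 CPM and GL2 by log2 0.67. The stomatal patterning peptide genes EPF1 and EPF2 fell (-1.49 and -1.44). Of 18 shoot meristem and leaf development genes 3 rose and 7 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.594). GRF5 rose by log2 1.59 and ANT by 0.47, and the boundary gene CUC3 and the YABBY gene AFO fell (-2.34 and -0.79). The median of this list, -0.19, turned to 0.23 under ribosomal protein scaling.

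For the lists where no other number is given, the counts adjusted over the list alone were those over all tested genes. With an estimated correlation, which rested on 2 residual degrees of freedom and so had little power, camera called none of the 25 lists (2 had an unadjusted p under 0.05). The fry test, which asks whether a list moves on balance without comparing it with other genes, gave an adjusted p under 0.05 for 11. Of the lists that camera called, storage lipid mobilisation and wall loosening did not pass it (fry adjusted p = 0.103 and 0.0564). The gibberellin, phase change, brassinosteroid and shoot meristem lists passed it without a camera call. Of the named genes, 12 lost their call in at least one fit that left out a library: TKL-1, ERF1, GAI, SUR1, LZF1, HB1, SPL4, SPL15, PHO1, OLEO4, ANT and GL2.

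**Figure D3:**
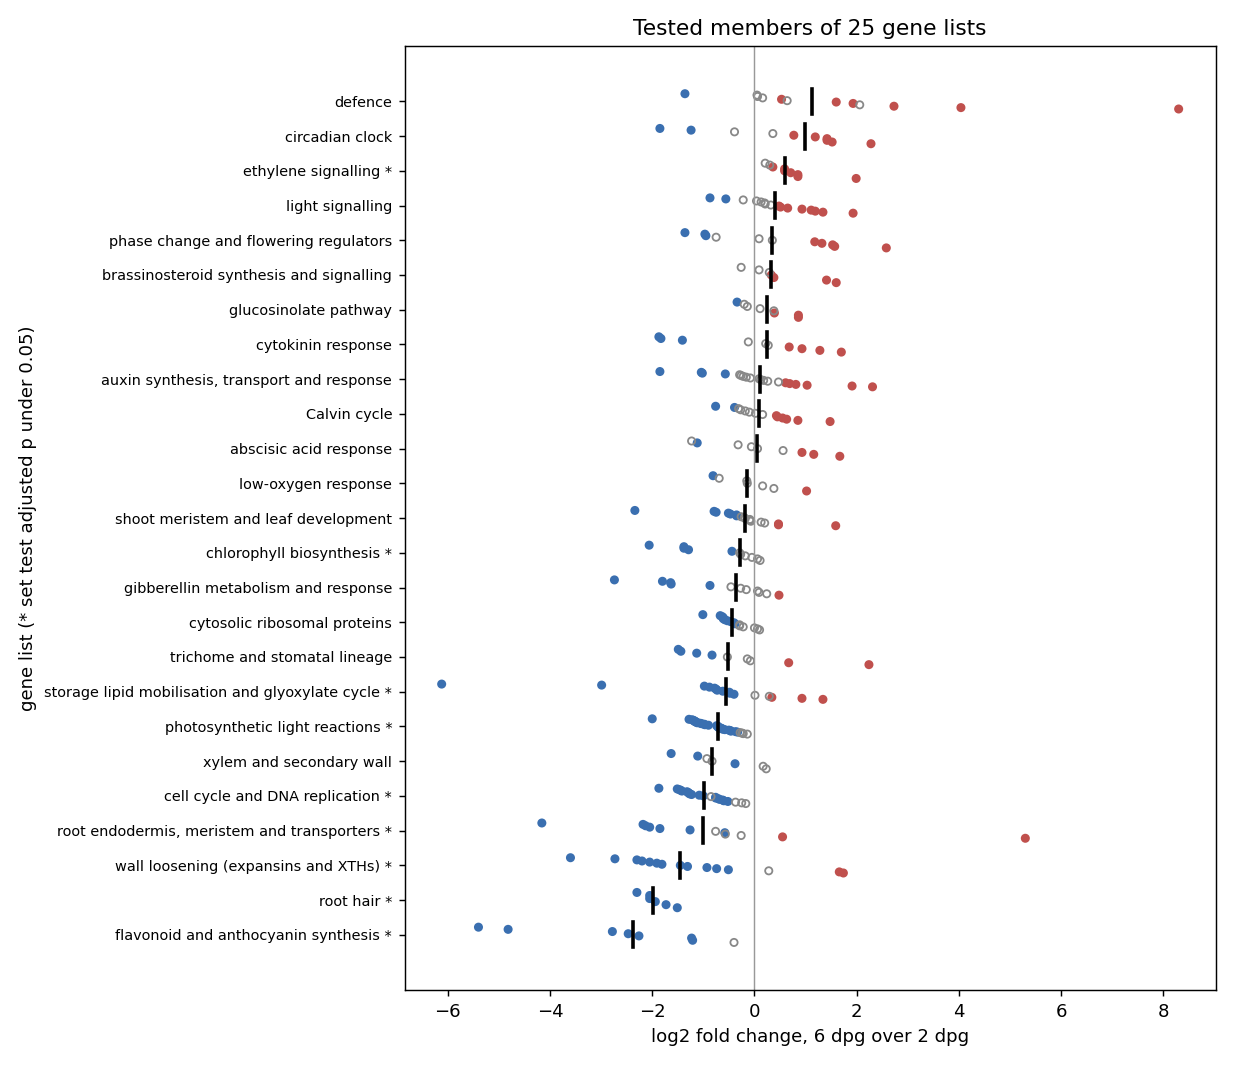
Log2 fold change, 6 dpg over 2 dpg (horizontal axis), of each tested member of 25 gene lists. Filled points passed an edgeR adjusted p of 0.05 (red higher, blue lower), open points did not, black bars are list medians, and asterisks mark the 9 lists called by camera with preset correlation, from flavonoid synthesis (median -2.37) to ethylene signalling (0.60), where the median of chlorophyll biosynthesis is above 0 under ribosomal protein scaling.

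The series is about transcription factor genes, and more of these rose than fell. In the authors' table of transcription factors and regulators, 1080 genes were tested and 733 changed, 520 higher and 213 lower. Adjusted over the list alone, 747 changed (530 and 217). Of these genes 48.1% were higher, against 26.8% of the 15080 other tested genes (Fisher's exact test, two-sided, p = 1.23e-46, odds ratio 2.53), and 19.7% were lower, against 29.0% (p = 1.7e-11, odds ratio 0.602). Genes are not independent, so these p-values are too small. Their median log2 fold change was 0.39, against -0.02 for other genes (camera p = 0.000113; p = 0.316 with an estimated correlation). At least 2-fold changes were found for 223 higher and 90 lower genes. All but 1 of the 1110 genes of that table held here had a read in these libraries, against 83.2% of other genes. The table may thus have been drawn up on these samples, and its counts are not independent evidence. With length-adjusted offsets the counts were 506 higher and 199 lower, with DESeq2 447 and 141, and under ribosomal protein scaling 632 and 64. In the authors' deposited table, 620 of these genes had an adjusted p under 0.05, 465 higher and 155 lower.

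Among transcription factor genes with a mean normalized count of 20 or more and no overlap between ages, the largest rise was that of SPL8 (AT1G02065), a squamosa promoter-binding-like gene, from 2 to 102 reads over both libraries of an age (51.9-fold, 95% exact interval 14.0 to 434). MYBL2 rose by log2 4.55 ± 0.16 (SE) and BHLH101 (AT5G04150), a regulator of iron uptake, from 0.0866 ± 0.0514 to 2.2 ± 0.361 CPM. The zinc finger gene AT1G29600 rose from 0.146 ± 0.149 to 3.17 ± 0.365 CPM. EBP (AT3G16770), a member of the ethylene response factors, was the most abundant of this group and rose from 189 ± 1.12 to 1679 ± 20.6 CPM. The NAC gene NAP (AT1G69490), a regulator of leaf senescence, rose from 3.37 ± 0.996 to 28.3 ± 1.72 CPM. The LIM gene PLIM2a rose from 0.379 ± 0.246 to 2.93 ± 0.741 CPM and the Myb-like gene AT3G11450 from 19.5 ± 9.16 to 148 ± 1.3 CPM. AGL44 (ANR1), a MADS-box gene of the root response to nitrate, rose by log2 2.92. HB-2 (AT4G16780), a homeodomain-leucine zipper gene of the shade response, rose from 4.58 ± 0.341 to 34.3 ± 0.163 CPM. The deepest falls under the same limits were those of ERF53 (AT2G20880), from 112 to 3 reads over both libraries of an age (36.7-fold, 95% exact interval 12.2 to 181), and PAP1. AT2G32550, an Rcd1-like gene, fell from 30.1 ± 3.82 to 2.14 ± 0.272 CPM and ETC1, a small MYB gene of epidermal patterning, from 3.83 ± 0.0864 to 0.382 ± 0.106 CPM. Of the MYB genes, MYB101 fell from 2.56 ± 0.146 to 0.309 ± 0.142 CPM and MYB102 by log2 fold change -2.69. MYB12, a regulator of flavonol synthesis, fell from 22.1 ± 0.837 to 4.66 ± 1.52 CPM. The zinc finger genes AT3G10470 and AT3G49930 fell (-2.25 and -2.19). The helix-loop-helix gene BS1 (AT1G74500) fell from 18.1 ± 2.97 to 3.91 ± 0.891 CPM. For these 20 genes the edgeR adjusted p lay at or under 0.000861.

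By family, 10 of the 33 families with 10 or more tested members were higher at 6 dpg than other genes by camera with preset correlation: MADS, SNF2, C3H, G2-like, HB, MYB, Trihelix, WRKY, PHD and Jumonji. Each had adjusted p = 0.788 with an estimated correlation, and no family was called that way (none had an unadjusted p under 0.05) or by fry after adjustment. Camera with an estimated correlation had little power here too, with 2 residual degrees of freedom. Of the 14 MADS-box genes 11 rose and none fell (median log2 1.42, adjusted p = 0.003). SVP (AT2G22540), a repressor of flowering, rose from 10.4 ± 0.795 to 30.0 ± 0.525 CPM. Of 24 G2-like genes 15 rose and 3 fell (0.00735), with AT2G38300 up by log2 2.30. Of 36 C3H zinc finger genes 18 rose and 4 fell (0.00443), with AT2G28450 from 10.9 ± 0.158 to 51.5 ± 2.27 CPM. Of 46 homeobox (HB) genes 24 rose and 7 fell (0.00883), with HB-2 at the smallest adjusted p, and with length-adjusted offsets 25 rose and 13 fell. For the MYB family that gene was MYBL2. The MYB family had 49 higher and 20 lower of 94 (0.0134), the WRKY family 19 and 5 of 37 (0.0152), with WRKY26 at log2 2.01. The Trihelix family had 9 and 0 of 16 (0.0141), with GT-1 at log2 1.40. Adjusted over the family alone, 1 more gene rose in each of the HB, MADS, MYB and PHD families and 1 more fell in SNF2.

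The remaining 3 called families, all of chromatin proteins, consist of long genes. Of 25 SNF2 chromatin remodelling genes 22 rose and 1 fell (adjusted p = 0.00417), including INO80 (AT3G57300), from 32.8 ± 13.1 to 121 ± 5.96 CPM. Of 23 PHD finger genes 17 rose and 2 fell (0.0191), with SHL1 up by log2 1.27. Of 12 Jumonji histone demethylase genes 9 rose (0.0407), with JMJ18 up by log2 1.17, a gene of whose span 21.3% is overlapped by another. The median lengths of the 3 families were 3879, 3090 and 3175.5 bp, and the length trend at their lengths was 0.42, 0.31 and 0.33. With length-adjusted offsets their adjusted p was 0.173, 0.284 and 0.384, and the other 7 families kept their call. The medians of SNF2, PHD and Jumonji went from 0.76 to 0.30, from 0.57 to 0.40 and from 0.75 to 0.45. With these offsets 12, 12 and 6 members were called higher and 3, 3 and 0 lower. Without 2 dpg replicate 1 the PHD and Jumonji calls were lost (0.0519 and 0.0839), and without 6 dpg replicate 2 the Jumonji call was lost (0.0801). The AP2-EREBP family, with 31 higher and 13 lower of 65 (0.0567), was called among genes with a mean normalized count of 20 or more (0.0394), with length-adjusted offsets (0.0112) and without 2 dpg replicate 1 or 6 dpg replicate 1 (0.046 and 0.0414). The C2H2 family, with 22 and 9 of 40 (0.0685), was called without 2 dpg replicate 2 or 6 dpg replicate 1 (0.0199 and 0.0477).

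**Figure D4:**
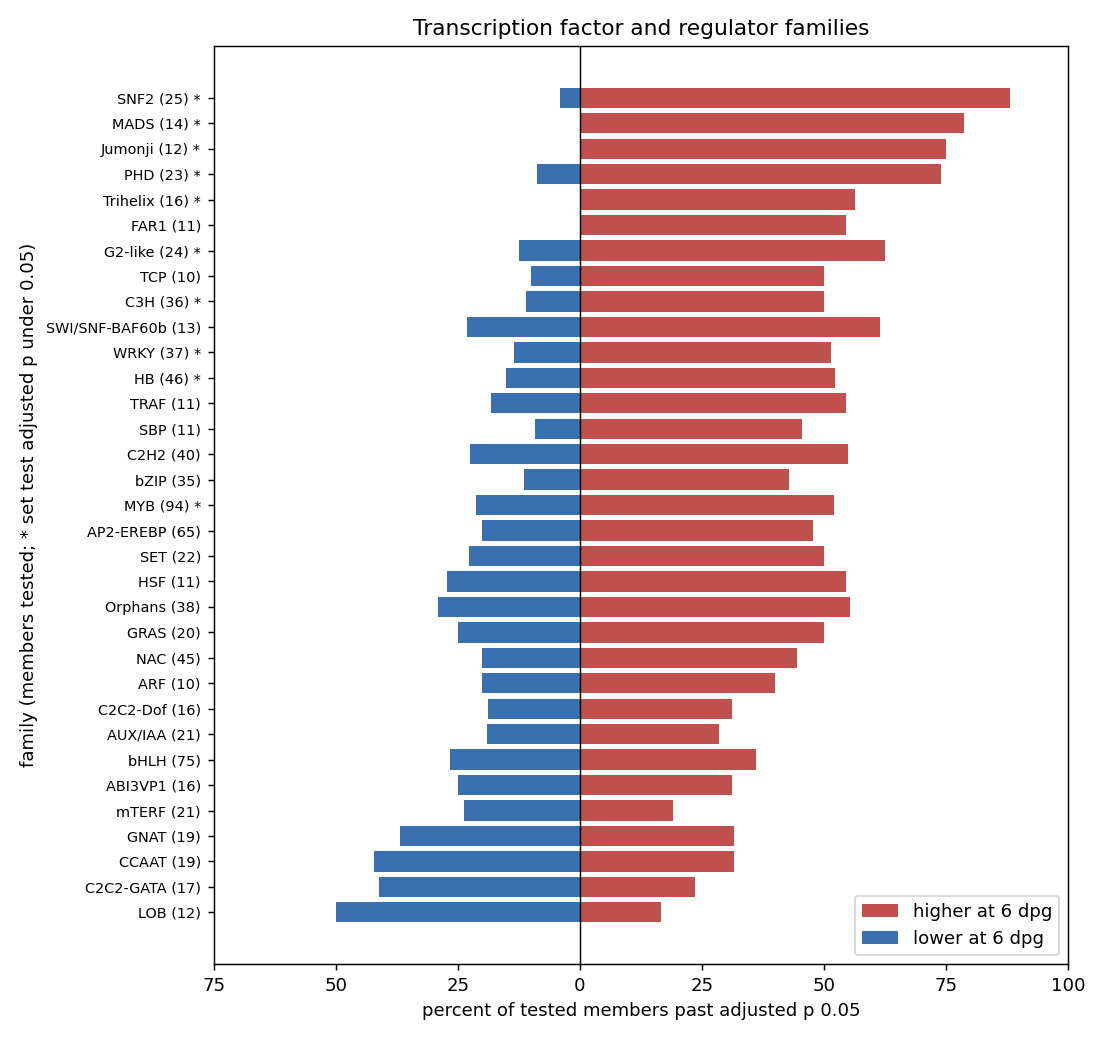
Percent of the tested members of each of 33 families that passed an edgeR adjusted p of 0.05, higher at 6 dpg to the right and lower to the left, with the number of tested members in parentheses. Asterisks mark the 10 families called by camera with preset correlation, among them SNF2 with 22 of 25 members higher and MADS with 11 of 14.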

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

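Scaling on ribosomal protein genes, column sums as library sizes and length-adjusted offsets were chosen after the data were seen. So were the fits of families and lists without one library. Column sums were bound to give nearly the same calls, because TMM factors are set relative to the library sizes supplied. The number of changed genes, 9153, stayed within 1.5 times of itself with RLE size factors (9166), DESeq2 (7391), no count filter (9664), a mean normalized count of 20 or more (8807), an adjusted p under 0.01 (6565), column sums as library sizes (9153), length-adjusted offsets (9142), ribosomal protein scaling (8223) and without one library (6951 to 9497). That for transcription factor genes, 733, ranged from 572 to 737 without one library, where the lone library of an age is assumed to vary like the pair of the other. Asking for an absolute log2 fold change of at least 1 left 3900 genes (1879 higher, 2021 lower) and 313 transcription factor genes (223 and 90), by construction. The number of lower transcription factor genes, 213, became 141 with DESeq2 and 134 at an adjusted p under 0.01; for DESeq2 the cause was not tested. Ribosomal protein scaling, which shifts the median by 0.44, left 1729 lower genes and 64 lower transcription factor genes, and under it the log2 fold changes of TKL-1 and SUR1 changed sign, to 0.035 and 0.096. With an estimated correlation camera called 0 lists and 0 families, where 2 lists and 0 families had an unadjusted p under 0.05. The estimate rested on 2 residual degrees of freedom, which leaves little power. A raised correlation cannot be the cause for the cell cycle, chlorophyll biosynthesis, root endodermis and root hair lists. Their estimates (-0.0437, -0.0272, -0.00119 and 0.00406) lay below the preset 0.01. In the other called lists and the called families the estimate lay above the preset. There a raised correlation and the few degrees of freedom cannot be told apart. A call lost in this way cannot count against a list or family, and whether the preset calls hold stays open. Without one library 9 to 12 lists and 9 to 12 families were called, with length-adjusted offsets 8 and 8, and at a mean normalized count of 20 or more 7 and 11.

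The ages share replicate numbers in the labels, but deviations of same-numbered libraries correlated at -0.00976 across genes, and no label says that a number marks a shared planting. With the replicate block 9099 genes were called (4555 higher, 4544 lower), 731 of them transcription factor genes, with 9 lists and 10 families; ethylene signalling was not among these lists (adjusted p = 0.0525) and defence was (0.0159). Of the 120 named genes, 118 kept their call with the block, 114 with DESeq2, 116 with length-adjusted offsets, 109 under ribosomal protein scaling and 112 to 118 without one library. Centring on the median moved no call, and camera, which compares a set with other genes, is unaffected by it. Removing organelle genes has no effect, since the table held none; a pseudocount of 0.1, recomputed adjustment of the deposited p, and Fisher tests and random lists for sets were meant for tables without counts and were not run.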

Other observations

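The tests of gene length and of green tissue below, and a split of the late embryogenesis genes, were chosen after the result was seen; those of the clock genes, of expression level and of seed transcripts were written down before. All 4 tested senescence genes were higher at 6 dpg: SEN1 (AT4G35770) from 45.0 ± 11.1 to 621 ± 74.1 CPM (SD, n = 2), NAP by log2 3.08, SGR1 (NYE1) by 0.36 and SAG13 (AT2G29350) from 1 to 78 reads over both libraries of an age, a ratio of 79.3 (95% exact interval 13.8 to 3170). Both tested genes of the endosperm and seed coat list fell, EPR1 (AT2G27380), an extensin-like gene of the endosperm, from 4.2 ± 0.382 to 0.0928 ± 0.0135 CPM and MUM4 by 0.70 on the log2 scale. None of the 3 tested heat shock genes passed the test (HSP70 27.2 ± 4.17 and 31.5 ± 15.7 CPM). Of 4 tested seed storage genes PAP85 and OLEO4 rose by log2 2.07 and 1.92, and SESA4 fell from 36 to 3 reads over both libraries of an age. These lists were too small for a set test.

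Among families with fewer than 10 tested members, for which no set test was run, all 6 TAZ genes, 7 of 8 CO-like genes and 4 of 5 BES1 genes were higher at 6 dpg with none lower. Others leaned the other way, with 1 higher and 4 lower of 9 zf-HD genes, 2 and 4 of 9 OFP genes and 1 and 3 of 5 CPP genes. Some low-oxygen and camalexin genes differed widely between the 6 dpg libraries: PDC1 stood at 10 ± 9.12 CPM, ADH1 at 15.4 ± 9.59 CPM and PAD3 at 5.27 ± 5.86 CPM. ADH1 also differed between the 2 dpg libraries (24.4 ± 14.9 CPM), and ERF73, in the same list, did not differ widely at 6 dpg (8.69 ± 0.0629 CPM). More genes had a read at 6 dpg (20020 and 20592) than at 2 dpg (18648 and 18600), although the 6 dpg libraries held fewer reads than their same-numbered 2 dpg libraries.

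Light-reaction genes were lower at 6 dpg, with a median of -0.71 (-0.29 under ribosomal protein scaling). A lower share of green tissue would lower Calvin cycle genes of the same cells alike, but their median lay higher by 0.80, at 0.09. The chlorophyll biosynthesis list, also of green cells, had a median of -0.29, between the medians of these lists. The comparison thus depends on the list chosen and cannot decide about green tissue. Gene length bias is argued against by a median of -0.58 that remained with length-adjusted offsets. For a harvest at another time of day, the 5 tested morning clock genes had a median of 1.42 and the 3 tested evening genes one of -1.24. The difference was 2.66, where a value over 1 had been predicted. The prediction held, but it did not ask whether such a shift lowers light-reaction genes. A contribution of harvest time to their fall therefore stays open. The labels give no hour of collection, and a clock phase that shifts with seedling age would give the same values. The age of the seedlings itself stays open, as untested.

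Transcription factor genes exceeded other genes by 0.41 in median log2 fold change. Gene length bias as the whole cause is argued against by the 0.35 that remained with length-adjusted offsets, and their median lengths were alike (1502 and 1524 bp). Expression level is argued against by a mean difference of 0.32 over 10 equal groups of genes ranked by expression, although in the 3 lowest groups it was -0.04, -0.26 and 0.11. For the SNF2 family, length bias cannot be told apart from a rise with age: its median fell from 0.76 (quartiles 0.54 and 0.99) to 0.30 (0.20 and 0.63), between the bounds set for either reading. Seedling age remains a candidate explanation for the rest, as a hypothesis. A harvest at another time of day, raised above for the light reactions, was not tested for these genes and cannot be told apart from age. The clock genes CCA1, LHY, RVE8, PRR7 and PRR9 were among the transcription factor genes that rose, and LUX among those that fell.

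Seed transcripts were scarce, yet 12 of the 14 listed seed genes were higher in 2 dpg replicate 2 than in replicate 1 (244 against 53 reads in all), SESA3 with 58 against 1, EM1 with 36 against 1 and OLEO1 with 30 against 2. Younger seedlings in replicate 2 would also hold more transcripts of lipid mobilisation, but the median log2 ratio of those 16 genes was -0.21, with 13 lower. The test fixed for seeds that had not germinated, on 51 other genes described as late embryogenesis abundant, failed: their median was 0.04, where over 1 had been predicted and under 0.5 was to count against it. That class proved too wide, since 42 of its genes had more than 5 reads over the 6 dpg libraries, and of the other 9, a split chosen after seeing the counts, 8 had a log2 ratio over 1. Of the 51 genes 26 were higher in replicate 2, and 13 (25.5%) had a log2 ratio over 1, against 1.62% of tested genes. The tested genes had passed a count filter that these did not have to pass. The rule fixed before counts against ungerminated seeds. With members going both ways, and a split chosen later, they cannot be told apart from other sources.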
